A study of Mus musculus with 23 samples.

How the data were processed

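Each of 23 arrays was hybridised with RNA of 1 bigenic and 1 monogenic mouse skin tumour of the same class. Per the labels' protocols, total RNA was isolated with TRIzol and a column clean-up, reverse transcribed with aminoallyl nucleotides and coupled to Cy3 or Cy5. The deposited value table holds 1 signed number per probe and array, from -11.3 to 11.2, which the authors deposited as ratios taken here to be on a log2 scale, since ratios on a log scale are centred on 0 and base 2 is usual. The log base, the numerator, the scanner, the background correction and the normalization are not given in the sources used here. The median of an array as deposited ran from -0.34 to 0.01, so the arrays had been centred or nearly so. Any loss of weak spots by the authors shows as missing values, which made up 0.24% to 29.9% of an array.

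All 23 value columns were matched to samples by name, and each sample was placed as papilloma or carcinoma by its labels, which also name both tumours and their dyes. On 18 arrays the bigenic tumour was in Cy3 and on 5 in Cy5. Ratios were turned so that arrays of both orientations run the same way, as Cy5 over Cy3 would read with the bigenic tumour on top, and the turn was checked on the 5 pairs measured in both orientations. Arrays of the same 2 extracts were averaged to 1 pair, giving 11 papilloma and 7 carcinoma pairs. Tumour names share numbers, such as 228A and 228B, and the labels do not say whether these came from 1 animal, so p-values measure the spread between tumour pairs and treat tumours as separate unless stated.

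Of 9596 probes, 7486 had 1 gene symbol in the platform annotation, 483 had several and 1627 had no annotation entry. Only probes with 1 symbol were named. Through the Entrez identifier 7395 of them were found in the reference gene table, and 0 symbols needed an update. Probes of 1 gene were averaged, which concerned 629 tested genes. The table held 6795 genes, of which 6413 were measured in at least 8 papilloma pairs and 5 carcinoma pairs and were tested.

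Each array was centred on its median. For each gene a generalised least squares model with 1 mean per class was fitted to the pairs, weighted by the number of arrays and with a covariance for pairs that share a tumour. The share of the variance due to tumours was estimated once over all genes by restricted maximum likelihood and came to 0, and to 0.2 in the model with a dye term. At 0 the main model in effect took the weighted pairs as independent, so its p-values make no allowance for shared tumours. The statistics were moderated with limma's eBayes and adjusted by the Benjamini-Hochberg method, with an adjusted p of 0.05 as the threshold. The comparisons were bigenic against monogenic in papillomas, the same in carcinomas, the difference between the classes as carcinoma minus papilloma, and the mean of both. A second model over the unaveraged arrays added a gene-specific dye term.

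The design, the rule for named genes, 27 gene lists and most alternatives were fixed before the data were examined. Added later were a tumour share of 0.2, a fit without the first range of experiment numbers, the range as a fixed term over pairs, and 3 settings of the dye-swap correlation. The rule takes Tgfb1 wherever it was measured. In each class it takes up to 12 genes each way past the threshold with the same sign in at least 80% of pairs and with a dye term. For the difference it takes the 5 largest each way past the threshold, for each list up to 4 members of smallest p, and, where fewer than 5 genes passed in a class, the 5 of smallest p each way. The lists covered TGF-beta pathway genes, matrix proteins, matrix proteases, mesenchymal transition, suprabasal differentiation, basal keratinocytes, the cell cycle, cytokines, neutrophils, macrophages, lymphocytes, MHC, interferon-induced genes, mast cells, fibroblasts, endothelium, skeletal muscle, adipocytes, erythroid cells, hair follicles, sebaceous genes, glycolysis and hypoxia, oxidative and xenobiotic response, immediate-early genes, ribosomal proteins, the respiratory chain, and hyaluronan and growth factors. Lists with at least 5 measured genes were tested with cameraPR on the moderated statistics, with a preset correlation of 0.01 and again with the correlation estimated from the residuals. That left 26 lists, because the erythroid list had 3 measured genes and was not tested. A list's median and test are over its genes, and a list mean per pair is over the genes measured in that pair.

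The models were tested on simulated data for 6413 genes with the real arrangement of pairs, 200 of them changed. In papillomas 48% of genes changed by 0.5 on the log2 scale were recovered, 96% of those changed by 1 and 100% of those changed by 2 or 3, with 4 false among 176 calls. In carcinomas 22%, 80%, 100% and 100% were recovered, with 4 false among 155. With a simulated tumour share of 0.3, 26%, 88%, 100% and 100% were recovered in papillomas, with 7 false among 164, and 10%, 76%, 100% and 100% in carcinomas, with 9 false among 152. At a share of 0.6 the recovery was 8%, 80%, 98% and 98% in papillomas, with 6 false among 148, and 10%, 66%, 94% and 98% in carcinomas, with 4 false among 138. Where a dye bias was simulated with no tumour share, 43 of 215 papilloma calls and 28 of 181 carcinoma calls were false, because most pairs have 1 orientation. For the difference between the classes, with no gene changed differently, 0 genes were called with or without that bias. The simulated noise was independent between genes, with 1 spread per gene over all pairs and no effect of experiment numbers. The simulated dye bias of a gene was the same in both classes. The simulation therefore cannot show how the difference behaves where arrays differ in spread or classes differ in experiment numbers.

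The alternatives were no centring, scaling to equal spread, quantile normalization, the dye term, the 5 pairs with both orientations alone, and the forward arrays alone. Independent pairs without weights for the number of arrays were tried as well. Other ways to treat shared tumours were the bigenic tumour or the linked group as the replicate, the monogenic tumour as a random block, and an animal effect for shared numbers. The animal effect was estimated at 0.15 of the variance, beside a tumour share of 0, with a higher restricted likelihood than the main model. Separate models for each class, robust eBayes, other filters on missing values, single probes, and leaving out each of 24 tumours were tried too, as were the array number and the range of experiment numbers as blocks. The number of arrays limits the precision. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, and Python 3.11.15 with matplotlib 3.10.9 for the plots. The genome build and sequences behind the probes were not used here.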

Results

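Skin tumours of bigenic mice, which carry a keratin 5-driven tetracycline transactivator and a doxycycline-inducible TGF-beta transgene, were set against tumours of monogenic mice that carry the transactivator alone. The tumours were raised in FVB mice with the carcinogen DMBA and the tumour promoter TPA, and both genotypes ate doxycycline chow for 48 h before harvest. They were papillomas, which are benign, or squamous cell carcinomas, with the stage checked on stained sections per the labels. The labels give weeks 12 to 14 for papillomas and weeks 25 to 35 for carcinomas. They also give TPA 2 times a week for 20 weeks and a mouse age of 7 to 12 weeks. Of 23 2-colour arrays, 14 held a bigenic and a monogenic papilloma and 9 a bigenic and a monogenic carcinoma. The papilloma arrays covered 8 bigenic and 7 monogenic tumours in 11 pairs of extracts, and the carcinoma arrays 5 bigenic and 4 monogenic tumours in 7 pairs. Of these 18 pairs, 5 were hybridised in both dye orientations, 3 of papillomas and 2 of carcinomas. Because tumours recurred across arrays, the pairs formed 4 linked groups of papillomas and 3 of carcinomas. An array held ratios for 6729 to 9573 of 9596 probes, with a median of 8872, and the SD of its log2 ratios ran from 0.29 to 1.2. The number of arrays limits the precision of what follows.

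The sources used here do not state which dye is the numerator of the deposited ratios, so each value below has a side instead of a direction. The positive side means more RNA in bigenic tumours if the ratios are Cy5 over Cy3, and less if they are Cy3 over Cy5. That the ratios followed the dyes was read from the pairs hybridised in both orientations. Among 73 probes that exceeded 4-fold on both arrays of such a pair, 68 had opposite signs as deposited. Across all probes, Pearson's r between the arrays of a pair was -0.33, 0.05 and -0.03 for the papilloma pairs and -0.21 and -0.12 for the carcinoma pairs, with a mean of -0.13, and Spearman's rho averaged -0.05. Over the 10% of probes with the largest ratios the mean r was -0.34. These are correlations across probes, which are not independent replicates. On 1 array, papilloma 12, the labels list the channels in the other order, and with its dyes followed it correlated at r = 0.43 with papilloma 2, which held the same bigenic tumour. A dye effect fitted per gene was past an adjusted p of 0.05 for 31 genes (limma), and positive in 27 of them.

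Tgfb1, which encodes the ligand named by the transgene, lay on the positive side on all 5 papilloma arrays that measured it, with a mean log2 ratio of 0.78 ± 0.69 (SD, n = 5). These arrays held 4 bigenic tumours, since 2 of them shared tumour 2145C. All 5 lay in the first range of experiment numbers, where arrays without a shared tumour correlated at a mean r of 0.33 across probes. The smallest two-sided p that an exact sign test of 5 arrays can give is 0.0625. On the 5 carcinoma arrays that measured it, Tgfb1 was positive on the 2 with the bigenic tumour in Cy5 and negative on the 3 with it in Cy3. The fitted carcinoma value was 0.03 ± 0.247 (SE), and the difference between the classes was -0.75 ± 0.349 (adjusted p = 0.645, limma). Its probe had too few values to enter the tests of all genes, and the sources used here do not say whether it reads the transgene. The papilloma values all came from arrays with the bigenic tumour in Cy3. With a dye term, the papilloma value was 1.33 ± 0.343 and the carcinoma value 0.13 ± 0.290, and that term rests on 2 carcinoma pairs. Tgfb3 stood at 0.38 ± 0.175 in papillomas, and the type II receptor Tgfbr2 at 0.51 ± 0.136 in carcinomas, positive on 9 of 9 arrays, neither past an adjusted p of 0.05 (0.49 and 0.136, limma).

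The papilloma comparison asked what TGF-beta induction changed in benign tumours. On the negative side were Cyp2s1, an epithelial cytochrome P450, at a log2 ratio of -0.70 ± 0.110 (SE) with 11 of 11 pairs negative, and Gstm1, a glutathione S-transferase, at -1.12 ± 0.206 with 10 of 10 negative. On the positive side were Sorcs2, a sorting receptor, at 0.70 ± 0.131 with 10 of 11 pairs positive, and Gem, a small GTPase, at 0.62 ± 0.119 with 11 of 11. The adjusted p was 0.0151 for Cyp2s1 and 0.046 for the other 3 (limma). These 4 were the genes past the threshold among 6413 tested, and 628 had an unadjusted p under 0.05. Just short of it lay Krt13, a keratin of stratified epithelia, at -2.45 ± 0.482 (adjusted p = 0.0514, 1 of 11 pairs positive), Gstm2 at -0.73 ± 0.148 (0.052), and Ppp1r14b, a phosphatase inhibitor, at 0.76 ± 0.151 (0.0514, 11 of 11 pairs positive). St3gal4, a sialyltransferase, stood at 0.79 ± 0.164 (0.0699), the urokinase gene Plau at 0.98 ± 0.210 (0.080), and Gpld1, a phospholipase, at -1.15 ± 0.256 (0.101, all limma), and the 2 probes of Gpld1 differed, at -1.48 and 0.04.

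The 4 papilloma calls sat close to the threshold. With a dye term 4 genes passed, of which Cyp2s1 and Sorcs2 were shared, while Gem had an adjusted p of 0.323 and Gstm1 of 0.139 (limma), and Irf1 (0.68, adjusted p = 0.035) and Bhlhe40 (1.11, 0.0364) were added. With equal spread on every array 19 genes passed, 9 positive, and with quantile normalization 27, 13 positive, each time with all 4 among them. Each tumour was also left out in turn, and because the classes share their estimate of spread this changed the count beyond the class of the tumour. The count was 0 without bigenic tumour 1762D, 1961B or 2145C or monogenic tumour 2000D, 2000E, 257CE or the monogenic tumour that the labels number control 7 (limma, 442 to 745 unadjusted), 1 without bigenic 170, 1995B, 228A or 228B or monogenic 2000J or 257A, 2 without bigenic 1684B, 228C, 236 or 237 or monogenic 241A or 257B, and 7 without bigenic 1687 or monogenic 221 or 242. Cyp2s1 passed in 17 of these 24 fits, with adjusted p up to 0.0932, Gstm1 in 8, Sorcs2 in 6 and Gem in 5.

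**Figure D1:**
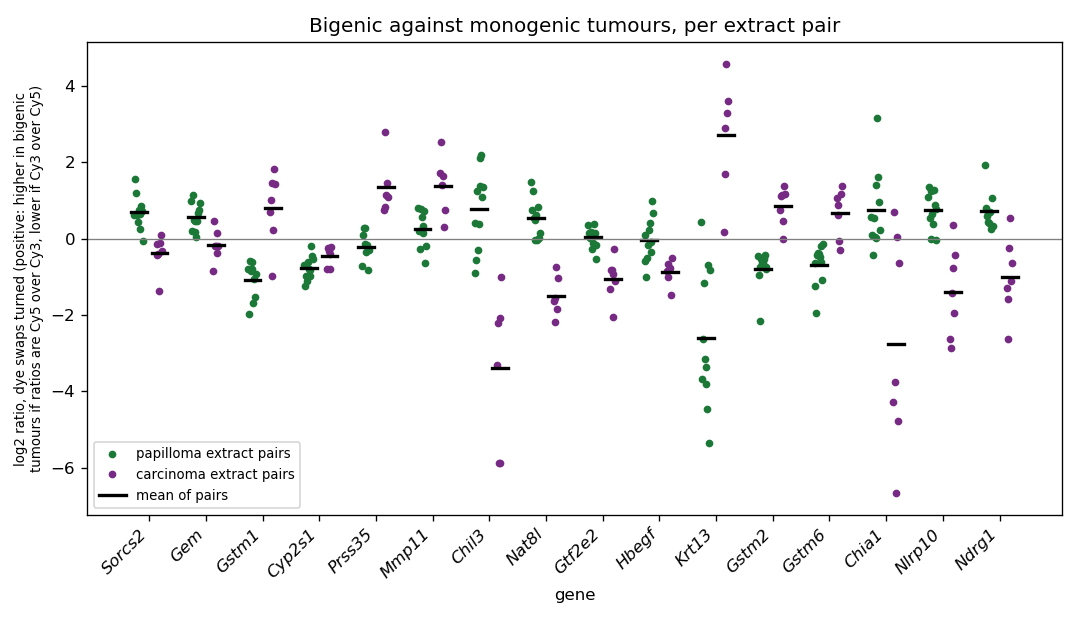
Turned log2 ratio (vertical axis) of 16 named genes in each extract pair, for 11 papilloma pairs and 7 carcinoma pairs, with a black line at the plain mean of the pairs of a class. Krt13 lay on the negative side in 10 of 11 papilloma pairs and on the positive side in the 6 carcinoma pairs that measured it.

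Gene groups fixed before the data were examined were tested with cameraPR, which asks whether a group shifted against all other genes. In papillomas the oxidative and xenobiotic response genes lay on the negative side, with 23 of 28 negative, a median log2 ratio of -0.26 and a list mean below 0 in all 11 pairs (adjusted p = 1.13e-07, cameraPR). Of these, 9 passed adjusted over the list alone, all negative, and 1 over all genes, Gstm1. They included Aldh3a1, an aldehyde dehydrogenase, at -1.23 ± 0.30, and Mt1, a metallothionein, at -0.89 ± 0.245. This was the one list that also passed with a correlation estimated from the residuals (adjusted p = 0.048 with an estimated correlation), which uses the residual correlation of its members instead of a preset 0.01. Once a dye term was added it no longer did (adjusted p = 0.0805 with an estimated correlation). Cell cycle and DNA replication genes lay on the same side, 31 of 35 negative with a median of -0.27 (adjusted p = 6.6e-09), and 4 passed adjusted over the list alone, among them Ccnd2, a D-type cyclin, at -0.56 ± 0.145 and Mcm5, a replication helicase subunit, at -0.58 ± 0.179. Suprabasal differentiation genes had a median of -0.53 with 9 of 11 negative (adjusted p = 0.000478), and 5 passed adjusted over the list alone, among them loricrin (Lor, -0.82 ± 0.221), Alox12b, a lipoxygenase of the barrier (-0.98 ± 0.268), and the suprabasal keratin Krt10 (-0.86 ± 0.348). Ribosomal protein genes had 22 of 24 negative at a median of -0.29 (adjusted p = 3.59e-06), with 0 members past adjusted over the list alone (limma, 4 unadjusted). The last 3 lists each had an adjusted p of 0.322 with an estimated correlation. Pair 1762D with 257B had the lowest oxidative, cell cycle and suprabasal means, at -1.18, -1.47 and -2.14. Its array, papilloma 2, had the widest SD, 1.2, and the lowest median, -0.34. In the 3 papilloma pairs with both orientations these means were -0.12, 0.0089 and -0.49. With each tumour left out in turn, the oxidative and cell cycle lists passed in 24 of 24 fits and the suprabasal list in 23.

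A further 3 papilloma lists lay on the negative side. Immediate-early and stress genes had 13 of 21 negative at a median of -0.15 (adjusted p = 0.00562, cameraPR), with 3 past adjusted over the list alone, among them the nuclear receptor Nr4a1 (-0.78 ± 0.197) and the chaperone Hspa5 (-0.77 ± 0.211). Basal and activated keratinocyte genes had 15 of 18 negative at a median of -0.08 (adjusted p = 0.00562), and adjusted over the list alone Krt13 and Krt6a (-0.39 ± 0.117) passed as negative and the laminin chain Lamb3 (0.66 ± 0.219) as positive. Both lists had an adjusted p of 0.322 with an estimated correlation. Respiratory chain genes had 17 of 21 negative at a median of -0.16 (adjusted p = 0.00223, and adjusted p = 0.349 with an estimated correlation), with 0 past adjusted over the list alone (limma, 2 unadjusted). With a dye term the keratinocyte and respiratory chain lists no longer passed (adjusted p = 0.556 and 0.536, cameraPR), and with equal spread on every array the keratinocyte list had an adjusted p of 0.0526. In the 3 papilloma pairs with both orientations the list means of the ribosomal and respiratory chain genes were positive, at 0.15 and 0.09. Over all 11 pairs the ribosomal mean was negative in 5 and the respiratory chain mean in 6. Over the ranges of experiment numbers both means were lowest in the first, at -0.64 and -0.37. They were 0.0011 and -0.06 in the second and -0.0071 and -0.005 in the third. In the third range 4 of 5 arrays were positive for each list, while pair 1762D with 257B stood at -1.17 for both. The immediate-early mean was also lowest in that pair, at -0.96.

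On the positive side in papillomas were groups of immune and protease genes. Interferon-induced genes had 14 of 16 positive and a median of 0.20 (adjusted p = 0.00111, cameraPR), and 3 passed adjusted over the list alone, the transcription factor Irf1 (0.51 ± 0.121), Ifi203 (0.52 ± 0.134) and Usp18, a protease that removes ISG15 (0.57 ± 0.186). With a dye term added, 8 of the 16 were positive at a median of 0.03, and the list still passed (adjusted p = 0.00954, cameraPR, and adjusted p = 0.386 with an estimated correlation). The interferon list mean was positive in 10 of 11 pairs and highest in pair 1762D with 257B, at 1.28. MHC and antigen presentation genes had 11 of 12 positive at a median of 0.26 (adjusted p = 0.00223), with 0 members past adjusted over the list alone (limma, 3 unadjusted), B2m standing at 0.68 ± 0.286. Inflammatory cytokines and chemokines had 23 of 30 positive at a median of 0.27 (adjusted p = 0.00111) and 0 past adjusted over the list alone (limma, 6 unadjusted), with the chemokine Ccl8 at 1.14 ± 0.320. The cytokine list mean was 0.0084, 0.55 and 0.33 in the first, the second and the third range of experiment numbers. Matrix proteases and inhibitors had 14 of 17 positive at a median of 0.25 (adjusted p = 0.00562), where Plau and the gelatinase Mmp9 (1.28 ± 0.287, 10 of 11 pairs) passed as positive adjusted over the list alone and the inhibitor Serpinb2 (-0.79 ± 0.204) as negative. Neutrophil markers had 8 of 10 positive at a median of 0.30 (adjusted p = 0.0175), with Mmp9, which that list also holds, as the 1 member past adjusted over the list alone. These 5 lists each had an adjusted p of 0.322 with an estimated correlation. Without monogenic tumour 257B, 7 papilloma lists passed in place of 14.

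Markers of other cell types moved with these papilloma groups. Macrophage markers had 20 of 22 positive at a median of 0.20 (adjusted p = 0.00562, cameraPR, and adjusted p = 0.434 with an estimated correlation), and skeletal muscle markers 18 of 19 positive at a median of 0.36 (adjusted p = 0.000908, and adjusted p = 0.322 with an estimated correlation), each with 0 members past adjusted over the list alone (limma, 1 and 2 unadjusted). The muscle list was positive in 8 of 11 pairs, and its members ranged widely between pairs, with desmin (Des) at 1.14 ± 0.509 and positive in 5 of 11. TGF-beta pathway genes were not past the threshold as a list (12 of 23 positive, adjusted p = 0.247), but 3 passed adjusted over the list alone, Bhlhe40 (0.80 ± 0.196), the inhibitory Smad gene Smad7 (0.61 ± 0.181) and Tgfbi (0.60 ± 0.18), all on the positive side. Among adipocyte markers (adjusted p = 0.607) Fabp4, a fatty acid binding protein, passed adjusted over the list alone at -1.38 ± 0.318, negative in 11 of 11 pairs, and among glycolysis and hypoxia genes (0.563) Ndrg1 did so at 0.80 ± 0.224. The other lists were not past the threshold, with adjusted p of 0.0626 for sebaceous genes, 0.0766 for mast cells, 0.165 for lymphocytes, 0.257 for hyaluronan and growth factor genes, 0.720 for fibroblasts, 0.810 for matrix proteins, and 0.972 for the mesenchymal, endothelial and hair follicle lists (cameraPR).

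The carcinoma comparison put the same question to malignant tumours, again with the positive side as defined above. Prss35, a protease-like secreted protein, stood at a log2 ratio of 1.33 ± 0.20 (SE) and the matrix metalloproteinase Mmp11 at 1.28 ± 0.229, each positive in 6 of 6 pairs. On the negative side were Chil3, a chitinase-like macrophage protein, at -3.53 ± 0.504, and Nat8l, which makes N-acetylaspartate, at -1.45 ± 0.213, each negative in 6 of 6 pairs. Gtf2e2, a subunit of the general transcription factor TFIIE, was at -0.95 ± 0.159 and Hbegf, a ligand of the EGF receptor, at -0.92 ± 0.18, each negative in 7 of 7. Adjusted p was 0.00303 for Chil3 and Nat8l, 0.00434 for Prss35, 0.00818 for Gtf2e2, 0.0208 for Mmp11 and 0.0382 for Hbegf (limma). These 6 were the genes past the threshold, against 694 with an unadjusted p under 0.05. With a dye term only Chil3 and Nat8l passed (adjusted p = 0.00461 and 0.00578), and the other 4 had adjusted p of 0.104 to 0.161 with their signs kept. Forward arrays alone gave 142 genes, the bigenic tumour as the replicate 113, the monogenic tumour as a block 51 and independent pairs without weights 44. Linked groups as replicates and classes fitted separately gave 0 (limma, 972 and 499 unadjusted). The count was 81 without monogenic tumour 257A, 23 without bigenic 236, 17 without bigenic 1687 or monogenic 221, 11 without bigenic 237 or monogenic 257B, and 2 without monogenic 241A. Chil3 and Nat8l lost the call only without 241A, at adjusted p of 0.187 and 0.194, Prss35 without 237 or 241A, at up to 0.178, and Gtf2e2 without 236 or 242, at up to 0.0719, while Mmp11 passed in 19 of 24 such fits and Hbegf in 10 (limma).

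Genes of the matrix and of macrophages lay together on the positive side in carcinomas. Fibrillar collagens and matrix proteins had 21 of 21 positive at a median log2 ratio of 0.43 (adjusted p = 4.39e-07, cameraPR), and 4 passed adjusted over the list alone, Nid1, a basement membrane linker (0.73 ± 0.210, 7 of 7 pairs), Mfap5, a microfibril protein (1.31 ± 0.388), Lox, which crosslinks collagen (0.62 ± 0.187), and Thbs2, a thrombospondin (0.89 ± 0.303, 7 of 7). Macrophage markers had 19 of 22 positive at a median of 0.51 (adjusted p = 1.53e-05), and adjusted over the list alone 6 passed as positive, among them lysozyme (Lyz2, 1.25 ± 0.369), the surface receptor Adgre1 (0.61 ± 0.208) and the signalling adaptor Tyrobp (0.81 ± 0.283), while Chil3 passed as negative. Fibroblast markers (9 of 10 positive, median 0.33, adjusted p = 0.0217) and mesenchymal genes (10 of 11, 0.21, 0.033) lay on the same side with 0 members past adjusted over the list alone (limma, 2 unadjusted in each), the smooth muscle protein Tagln standing at 0.82 ± 0.264. These 4 lists had an adjusted p of 0.349 with an estimated correlation. Matrix proteases had 12 of 17 positive at a median of 0.27 (adjusted p = 0.0217, and adjusted p = 0.561 with an estimated correlation), with Mmp11 past adjusted over the list alone. The pairs of 170 and 1684A share monogenic tumour 242. Their protease means were 1.49 and 1.11, against -0.27 to 0.21 in the others. The macrophage means (1.56 and 0.82) and matrix means (1.01 and 0.96) were also highest there. In the 2 carcinoma pairs with both orientations the protease mean was -0.27 and the matrix mean 0.11. Other lists hold 5 of the 10 fibroblast genes, 3 of the 21 matrix genes and 3 of the 11 mesenchymal genes.

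Proliferation and hypoxia genes lay on the negative side in carcinomas. Cell cycle and DNA replication genes had 33 of 35 negative at a median of -0.31, and the list mean was negative in 7 of 7 pairs (adjusted p = 5.32e-06, cameraPR). The proliferation marker Mki67 (-0.85 ± 0.226), the checkpoint gene Mad2l1 (-0.82 ± 0.230) and the centromere protein Cenpa (-0.84 ± 0.246) passed adjusted over the list alone. Glycolysis and hypoxia genes had 10 of 12 negative at a median of -0.29 (adjusted p = 0.00276), with 5 past adjusted over the list alone, among them Vegfa (-0.97 ± 0.245), the pyruvate kinase Pkm (-0.63 ± 0.198) and the glucose transporter Slc2a1 (-0.83 ± 0.294). The glycolysis list mean was -1.73 in pair 1687 with 221 and positive in 236 with 257A (0.11) and 237 with 257A (0.20). This list passed in 22 of 24 fits with a tumour left out, but not in carcinomas of the second range of experiment numbers (adjusted p = 0.261, cameraPR). Basal and activated keratinocyte genes had 13 of 18 negative at a median of -0.30 (adjusted p = 0.0217), but members went both ways. Adjusted over the list alone 5 were negative, among them the EGF receptor ligands Hbegf and Tgfa (-0.76 ± 0.196) and the integrin Itgb4 (-0.61 ± 0.175), and 2 positive, Krt13 (3.01 ± 0.637) and Krt15 (0.75 ± 0.222). These 3 lists had an adjusted p of 0.349 with an estimated correlation, and the keratinocyte list did not pass with a dye term (adjusted p = 0.242, cameraPR). In the 2 carcinoma pairs with both orientations the cell cycle, glycolysis and keratinocyte means were -0.16, -0.04 and 0.22. Of the 26 lists, 9 passed in carcinomas, and the count was 15 without bigenic tumour 236, 6 without monogenic 242, 5 without bigenic 1684A, bigenic 1687 or monogenic 221, and 4 without bigenic 170.

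Markers of other tissues varied widely between carcinoma pairs. Skeletal muscle markers had 17 of 19 positive at a median of 0.28 (adjusted p = 0.0398, cameraPR, and adjusted p = 0.797 with an estimated correlation), with 0 past adjusted over the list alone (limma, 1 unadjusted), and the call was lost with no centring, equal spread or quantile normalization (adjusted p = 0.0617, 0.11 and 0.253). Their list mean ran from 2.40 in pair 1687 with 221 and 1.54 in pair 170 with 242 to -0.76 in pair 236 with 257A and -1.26 in pair 237 with 257A. The macrophage list mean was 0.78 and 1.56 in the first 2 of these pairs and -0.11 and 0.06 in the last 2, and the matrix list mean 0.56 and 1.01 against -0.13 and 0.03. The cell cycle list mean was -0.58 and -0.45 against -0.24 and -0.11. In the 2 carcinoma pairs measured in both orientations the macrophage mean was -0.05 and the muscle mean -0.39. TGF-beta pathway genes were not past the threshold (16 of 23 positive, adjusted p = 0.0779), although with a dye term they were (adjusted p = 0.0211, cameraPR, and adjusted p = 0.0883 with an estimated correlation), and adjusted over the list alone 5 of them passed in opposite directions. The receptor Tgfbr2, the matrix protein Tnc (0.84 ± 0.260) and the latency binding protein Ltbp2 (0.63 ± 0.224) were positive, and the repressors Klf10 (-0.74 ± 0.163) and Bhlhe40 (-0.77 ± 0.245) negative in 7 of 7 pairs.

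**Figure D2:**
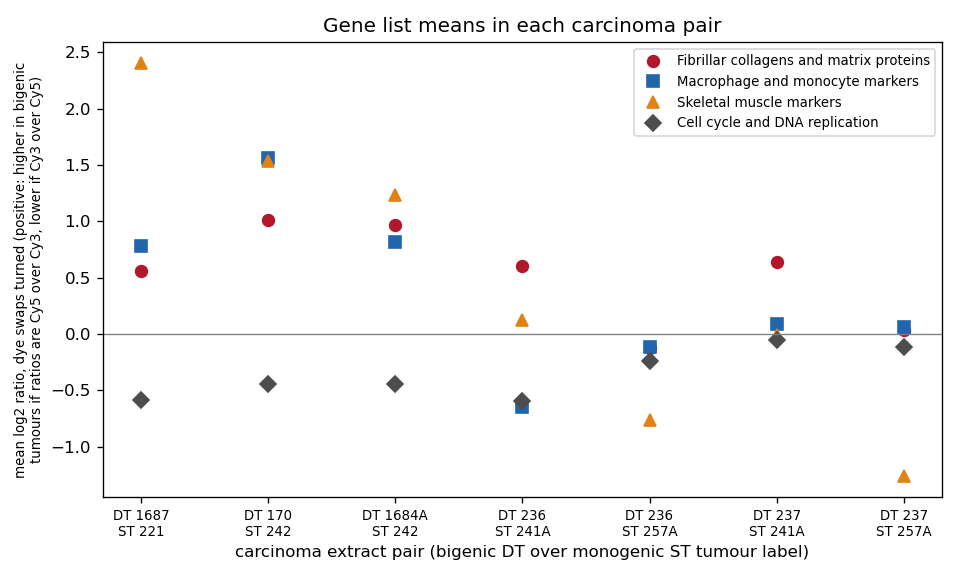
Mean log2 ratio (vertical axis) of the matrix, macrophage, skeletal muscle and cell cycle lists in each of 7 carcinoma extract pairs. The cell cycle mean lay below 0 in all 7 pairs, while the muscle mean ran from -1.26 to 2.40.

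Members of other lists in carcinomas passed adjusted over the list alone while their lists did not pass. They were the suprabasal keratin Krt77 (0.77 ± 0.215) and the cornified envelope gene Sprr2a1 (-0.76 ± 0.246) for suprabasal genes (adjusted p = 0.705, cameraPR), the alarmin S100a8 (-0.80 ± 0.253) for neutrophils (0.419), Irf1 (-0.55 ± 0.151) for interferon genes (0.688), Trps1 (0.83 ± 0.179) for hair follicle genes (0.353), and Igf1 (0.92 ± 0.212) with Vegfa for hyaluronan and growth factor genes (0.569). Among oxidative and xenobiotic response genes (0.409), Gstm1 (0.86 ± 0.238) and Gstm2 (0.82 ± 0.185) were positive and thioredoxin (Txn1, -1.04 ± 0.235, 7 of 7 pairs) negative. The lists without such a member had adjusted p of 0.122 for cytokines, 0.252 for mast cells, 0.353 for the endothelial, ribosomal and respiratory chain lists, 0.494 for lymphocytes, 0.522 for MHC genes, 0.553 for adipocytes, 0.908 for immediate-early genes and 0.947 for sebaceous genes (cameraPR). The median, the mean and the test differed in sign in papillomas for the mesenchymal and hair follicle lists, in carcinomas for the immediate-early, sebaceous and hyaluronan lists, and in the difference between classes for the protease, basal keratinocyte, mast cell, adipocyte and hyaluronan lists, none of them past the threshold in that comparison.

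**Figure D3:**
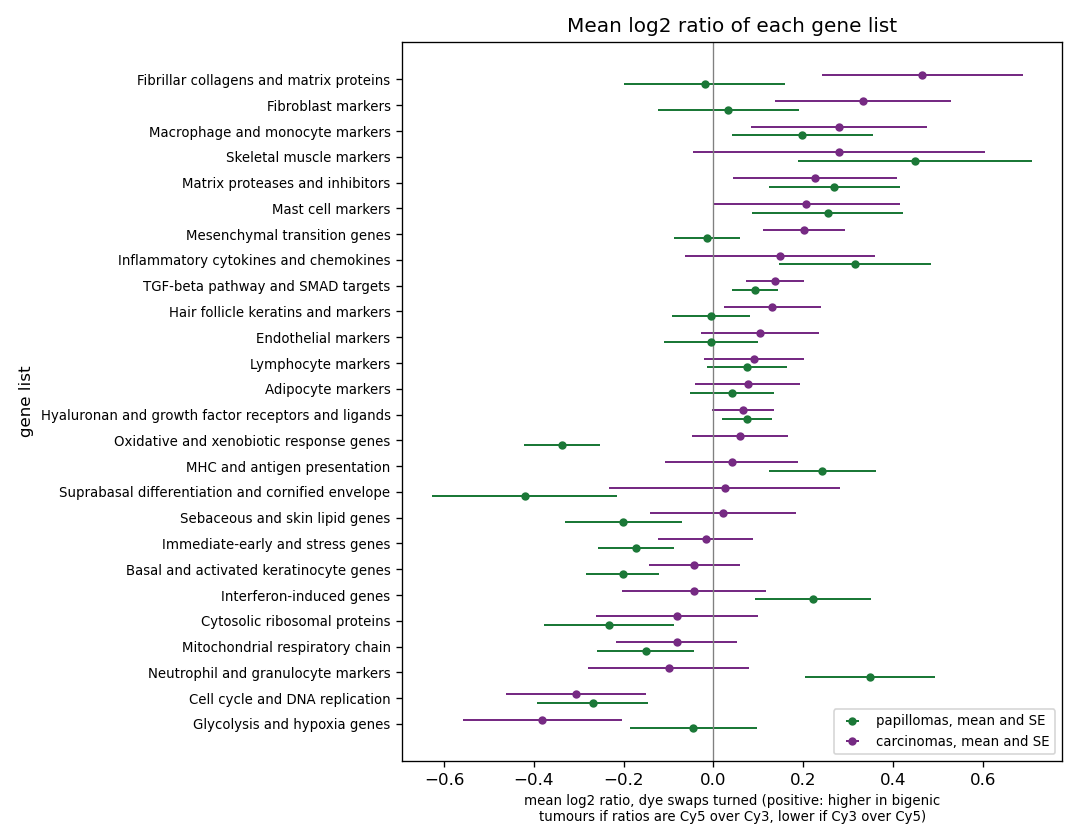
Mean log2 ratio and SE (horizontal axis) of 26 gene lists in papillomas (11 pairs) and carcinomas (7 pairs). The matrix list mean was -0.02 in papillomas and 0.47 in carcinomas, and the oxidative and xenobiotic list mean -0.34 and 0.06.

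The last comparison tested whether the ratios of bigenic to monogenic tumours differed between carcinomas and papillomas. Class goes with the week of the tumours, 12 to 14 for papillomas against 25 to 35 for carcinomas. It may so go with exposure to TPA, which was given for 20 weeks, and these cannot be told apart. Krt13 differed most, at 5.46 ± 0.799 (SE) as carcinoma minus papilloma on the log2 scale, from -2.45 in papillomas to 3.01 in carcinomas, where it was positive in 6 of 6 pairs. The glutathione S-transferases Gstm1 (1.98 ± 0.315), Gstm2 (1.55 ± 0.237) and Gstm6 (1.30 ± 0.267) took the same course, negative in every papilloma pair that measured them and positive in 6, 6 and 5 of 7 carcinoma pairs, and Prss35 differed by 1.59 ± 0.269. In the other direction were the chitinase-like Chil3 (-4.40 ± 0.632) and the chitinase Chia1 (-3.49 ± 0.763), Nat8l (-2.04 ± 0.268), the NOD-like receptor Nlrp10 (-2.03 ± 0.361) and the stress-induced Ndrg1 (-1.64 ± 0.350). Adjusted p ran from 0.000962 for Nat8l to 0.046 for Chia1 (limma). In all, 23 genes passed, 6 positive and 17 negative, and 495 had an unadjusted p under 0.05. Once a dye term was added 25 passed, 20 of them shared. Equal spread on every array gave 16 genes, 6 positive, and quantile normalization 25, 10 positive. With the range of experiment numbers in the labels as a fixed term over the 18 pairs, a choice made after the data were seen, 7 genes passed (limma, 709 unadjusted), 0 of them among the 23. The 23 kept their signs and had unadjusted p under 0.05, at adjusted p of 0.0513 to 0.345. Their differences were a median of 0.96 times those without the term, from 0.65 to 1.36 times, and their SE a median of 1.39 times. Gstm1 was then 2.02 ± 0.423, Prss35 2.09 ± 0.497, Chil3 -5.20 ± 1.19 and Nat8l -1.96 ± 0.507, whereas Krt13 was 3.54 ± 1.44 and Chia1 stood at -2.58 ± 1.00.

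The difference count also depended on single tumours. It was 1 without monogenic tumour 241A, 3 without bigenic 237, 4 without monogenic 257B, 9 without bigenic 1684B or 2145C or monogenic 2000D, 12 without bigenic 170 or monogenic 2000E, 13 without bigenic 1995B, 228A or 228B or monogenic 2000J, and 14 without bigenic 1684A or 236. Chil3 and Nat8l lost the call only without 241A (adjusted p = 0.054 for both, limma), whereas Gstm6 passed in 11 of 24 such fits, Ndrg1 in 7 and Chia1 in 4. Krt13 and Gstm2 lost it without 237 or 241A, at adjusted p up to 0.0633 and 0.0706, and Gstm1 without 237 or 257B, at up to 0.0801 (limma).

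As groups, 4 of 26 lists passed for the difference between the classes at the preset correlation. Of 35 ways to split the linked tumour groups, the real one among them, 33 gave at least 4 lists, so chance cannot be excluded here. Matrix proteins were shifted to the positive side in carcinomas relative to papillomas, 19 of 21 with a median difference of 0.62 (adjusted p = 1.35e-05, cameraPR, and adjusted p = 0.699 with an estimated correlation), with 0 members past adjusted over the list alone (limma, 5 unadjusted). Oxidative and xenobiotic genes had 23 of 28 positive and a median of 0.29 (adjusted p = 5.31e-05, and adjusted p = 0.330 with an estimated correlation), and Gstm1, Gstm2 and Aldh3a1 (1.63 ± 0.469) passed as positive adjusted over the list alone and Txn1 (-1.17 ± 0.306) as negative. Suprabasal genes had 8 of 11 positive and a median of 0.47 (adjusted p = 0.0229), with Lor (1.44 ± 0.353) and Krt10 (1.53 ± 0.556) positive and Sprr2a1 (-0.86 ± 0.315) negative adjusted over the list alone. Interferon-induced genes had 9 of 16 negative and a median of -0.33 (adjusted p = 0.0384), and 0.0552 with no centring, where Irf1 (-1.06 ± 0.194) and Ifi203 (-0.87 ± 0.214) passed adjusted over the list alone. The last 2 lists had an adjusted p of 0.699 with an estimated correlation. With the range of experiment numbers as a fixed term only the matrix list of these 4 passed (0.42, adjusted p = 0.0289, cameraPR, and adjusted p = 0.870 with an estimated correlation). The suprabasal median was then 0.58 (adjusted p = 0.238), the interferon median -0.28 (0.511) and the oxidative median 0.02 (0.345). In that model 3 other lists passed on the negative side. They were glycolysis and hypoxia genes at -0.79 (adjusted p = 6.9e-07, and adjusted p = 0.0462 with an estimated correlation), against -0.23 (0.0664) without the term, cell cycle genes at -0.41 (0.00147) against -0.05 (0.924), and ribosomal genes at -0.32 (0.0121) against 0.17 (0.0664). The last 2 had an adjusted p of 0.870 with an estimated correlation. None of the 3 passed within the second range (adjusted p = 0.461, 0.0801 and 0.689), and the 1 carcinoma array of the third range had glycolysis, cell cycle and ribosomal means of -1.73, -0.58 and -0.49. In the 5 pairs with both orientations the matrix difference turned to -0.12. The number of lists was 2 without bigenic tumour 1762D, 7 without bigenic 1684B or 170 or monogenic 2000E, 241A or 257CE, 8 without bigenic 2145C, 9 without monogenic 242, and 10 without bigenic 236 or monogenic 257A.

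On average over both classes, Cyp2s1 was the 1 gene past the threshold, at -0.60 ± 0.091 (SE, adjusted p = 0.00988, limma), against 807 genes with an unadjusted p under 0.05. Cyp2s1 was negative in 11 of 11 papilloma pairs and 6 of 6 carcinoma pairs. With an animal effect for shared numbers, or the bigenic tumour or linked groups as the replicate, 0 genes passed (limma, 535, 1346 and 1065 unadjusted). Forward arrays alone gave 216. The count was 36 without monogenic tumour 257A, 4 without monogenic 257CE, 2 without bigenic 228B and with quantile normalization (1 positive), and 0 without bigenic 2145C or 236 or monogenic 2000E, 241A or 242 (limma, 421 to 880 unadjusted). The lists past the threshold numbered 15, 9 positive and 6 negative, but with an estimated correlation 0 lists passed. With a dye term 14 lists passed at the preset correlation and 1 with an estimated one. Cell cycle genes led the 15, with a median of -0.28 and 10 negative members past adjusted over the list alone (adjusted p = 8.87e-12, cameraPR, and adjusted p = 0.269 with an estimated correlation). TGF-beta pathway genes were among the 15, at a median of 0.19 (adjusted p = 0.0216, and adjusted p = 0.269 with an estimated correlation), with Klf10 (-0.52 ± 0.105) the 1 member past adjusted over the list alone. The fold changes of the classes correlated weakly across 6413 genes (r = 0.12, Spearman's rho = 0.19), and with a dye term not at all clearly (r = -0.06). Flipping the signs of linked tumour groups gave an r as far from 0 in 20 of 32 patterns, and genes are not independent replicates. Without monogenic tumour 242 the correlation was -0.05.

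Experiment numbers in the labels fell into 3 ranges, taken here as batches, with 5, 4 and 5 papilloma arrays in the first, the second and the third, and 8 and 1 carcinoma arrays in the second and the third. The 3 swapped papilloma pairs had 1 orientation in the second range and the other in the third, so that dye and range are mixed there. Forward arrays that shared no tumour correlated at a mean r of 0.33 across probes within the first range and 0.02 between ranges. Within ranges, Cyp2s1 in papillomas was -0.92, -0.31 and -0.79 from the first to the third range, Gstm1 -0.71, -1.33 and -1.32, Sorcs2 0.73, 0.31 and 0.98, and Gem 0.28, 0.84 and 0.79. Each array was taken as a replicate within ranges, although some arrays share a tumour or, in carcinomas, the same extracts. P-values within ranges may therefore be too small. Counts within ranges were 23, 2 and 0 genes in papillomas (limma, with 154 at an unadjusted p under 0.05 in the third range) and 4 in the carcinomas of the second. Of the 14 papilloma lists, 14, 14 and 12 lay on the same side within the ranges and 6, 6 and 11 passed there, and of the 9 carcinoma lists 9 lay on the same side in the second range and 6 passed. The carcinoma glycolysis, basal keratinocyte and muscle lists did not pass there (adjusted p = 0.261, 0.0695 and 0.761, cameraPR). With an estimated correlation 0, 0 and 2 of the papilloma lists passed within the ranges (cameraPR), the 2 being cytokines and neutrophil markers, and 0 of the carcinoma lists. The ribosomal and respiratory chain lists passed in papillomas of the first range (adjusted p = 5.13e-11 and 0.000132, cameraPR, and adjusted p = 0.370 and 0.456 with an estimated correlation) but not of the second (0.592 and 0.322) or the third (0.976 for both). Cytokines did not pass in the first (0.638) but did in the second (0.000942, and adjusted p = 0.111 with an estimated correlation) and the third (0.000187, and 4.5e-05 with an estimated correlation). The cell cycle list mean was -0.47, -0.0094 and -0.27 over the ranges. The matrix list mean was 0.44 in carcinomas of the second range, and -0.17, -0.02 and 0.16 in papillomas. Between 8 carcinoma and 4 papilloma arrays of the second range, 0 genes passed for the difference (limma, 431 unadjusted), with Krt13 at 4.63 ± 0.909, Gstm1 at 2.18 ± 0.515, Chil3 at -4.88 ± 0.844 and Nat8l at -1.87 ± 0.355. The 23 genes kept their signs there, 20 of them with an unadjusted p under 0.05, at a median of 0.87 times their difference over all pairs and with a median SE 1.44 times as large. All 4 difference lists lay on the same side there, and the matrix (adjusted p = 4.93e-06) and suprabasal lists (0.0142) passed, while the oxidative (0.139) and interferon lists (0.144, cameraPR) did not. With an estimated correlation neither of the first 2 passed, at an adjusted p of 0.576 for matrix and 0.609 for suprabasal genes.

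With the range as a random block, and each of the 23 arrays counted as a replicate although they come from 18 pairs, 14 genes passed in papillomas, 26 in carcinomas and 47 for the difference, against 15, 29 and 49 for the same arrays without the block (limma). These p-values are too small because swapped arrays and shared tumours are counted as separate. Only the counts with and without the block are compared here. The correlation within ranges was estimated at 0.0056, so the block could change little. These counts and lists therefore do not show that the results are free of the range. The lists past the threshold in the pairs stayed so with the block, at 14 in papillomas, 9 in carcinomas and 4 for the difference (cameraPR), and with an estimated correlation 1, 0 and 0 of them did. The matrix difference was 0.62 with the block (adjusted p = 0.588 with an estimated correlation), the oxidative 0.29 (0.207), the suprabasal 0.47 (0.630) and the interferon difference -0.33 (0.630, all with an estimated correlation). Leaving out the first range, a choice made after the data were seen, gave 1 gene in papillomas, 3 in carcinomas and 3 for the difference, with 12, 9 and 6 lists.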

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

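Of the tests in this part, those of dye bias as the whole of a change, of dye bias across a whole list, of the range as a fixed term, and of stromal and leukocyte shares, with the shorter neutrophil list among them, were chosen after the results were seen.

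The sign of the ratios is the first pattern, since it sets the direction of every value. If the ratios were Cy5 over Cy3, the ligand gene Tgfb1 should lie on the positive side once dye effects are removed, and its mean over both classes with a dye term was 0.73 ± 0.235 on the log2 scale, which argues against Cy3 over Cy5. With that reading the positive side is more RNA in bigenic tumours, so that Cyp2s1 and Gstm1 would be lower in bigenic papillomas, and matrix genes higher and Chil3 lower in bigenic carcinomas. This rests on 1 probe, on a dye effect taken from 2 carcinoma pairs, and on 5 papilloma arrays of 4 bigenic tumours, all in the first range of experiment numbers, since the 5 carcinoma arrays were positive on the 2 with the bigenic tumour in Cy5 and negative on the 3 with it in Cy3. Whether the probe reads the transgene stays open, so the direction is likely but not settled.

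Genes past the threshold within a class are the second pattern, weighed against gene-specific dye bias because most pairs were measured in 1 orientation. Once a dye term was added, 0 of 4 papilloma genes and 0 of 6 carcinoma genes came within 2 SE of 0, and 2 and 2 of them still passed the threshold. This cannot decide whether such bias is the whole of the change, because the genes were chosen on these same arrays. The term rests on 5 swapped pairs, and in the papilloma ones dye and range of experiment numbers are mixed. A contribution of dye bias cannot be told apart, since over the called genes the ratios of pairs never swapped correlated with the dye effect of swapped pairs at r = -0.39 in papillomas and 0.61 in carcinomas, on 4 and 6 genes. Across all genes that r was 0.11 and 0.37. An effect of the transgene on these genes stays open as a hypothesis, as do differences between tumours of different animals, which were not tested.

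Matrix and macrophage genes on the same side in carcinomas are the third pattern. Dye bias across the lists is argued against by their means with a dye term, 1.15 times that without for matrix and 1.37 times for macrophage genes, and by fitted dye effects of 0.07 ± 0.142 and 0.05 ± 0.119 where -0.47 and -0.28 would cancel the means, although the 2 carcinoma pairs with both orientations alone gave means of 0.11 and -0.05. Matrix genes exceeded endothelial markers by 0.36 ± 0.069 on the log2 scale, in 7 of 7 carcinoma pairs, so the 2 lists did not shift equally. This cannot exclude a different share of all stromal cells, because lists of different genes need not follow such a share equally. These SE take the 7 pairs as independent, although they reuse 5 bigenic and 4 monogenic tumours. A larger share of fibroblasts alone may account for the gap, with fibroblast markers 0.23 ± 0.059 above endothelial ones. For macrophage genes a different share of all leukocytes cannot be told apart, since they exceeded lymphocyte markers by 0.19 ± 0.169, in 6 of 7 pairs, and neutrophil markers by 0.38 ± 0.165, in 5 of 7, but by 0.082 ± 0.217, in 3 of 7, once 4 neutrophil genes that keratinocytes also express were left out. A response of matrix genes within fibroblasts or tumour cells to TGF-beta is 1 hypothesis. It stays open beside the share of all stromal cells, of fibroblasts and of muscle in each tumour piece.

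The counts were set against regroupings of the linked tumour groups. For the difference between the classes, 1 of 35 splits gave as many genes, the real one with 23, and the highest of the others gave 9. That share, 0.0286, is the smallest that 35 splits can give. It argues against chance in how these 7 linked groups are split, but does not exclude it. The splits take the groups as alike and separate, although tumour numbers such as 1684A and 1684B are shared across groups. The first range of experiment numbers also holds papillomas only. With the range of experiment numbers as a fixed term 7 genes passed, 0 of them among the 23, and within the second range 0 did (limma, 431 unadjusted). Whether the range is the whole of the difference cannot be decided here, because the 23 genes were chosen on these same pairs. With that term 0 of the 23 came within 2 SE of 0, at a median of 0.96 times their differences without it and an SE 1.39 times as large. Within the second range 1 of the 23 did, and the median was 0.87 times. The calls thus ended mainly through larger errors, although Krt13 went from 5.46 ± 0.799 to 3.54 ± 1.44. A part of the difference that goes with the range stays open. An animal effect, which had a higher restricted likelihood than the main model, left 9 genes, and linked groups as replicates 0 (limma, 492 unadjusted). For the lists that differed, chance cannot be excluded, as 33 of 35 splits gave at least the real 4 with a median of 8 among the others and a highest of 17. These lists were counted at the preset correlation of 0.01, and whether the correlation of their members or a structure among the tumours gives such counts was not tested. For the mean over both classes 27 of 64 sign patterns gave at least the real 1 gene, and the highest gave 25. Turning the sign of 1 whole class is among these patterns and gives the difference between the classes, with its 23 genes. High counts are thus partly built in, and chance cannot be excluded there. Within a class the patterns are too few for a share under 0.05. In papillomas 1 of 8 gave as many genes, with the real 4 and the highest other 0 (limma), and in carcinomas 3 of 4, with the real 6 and the highest other 10.

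Genes whose response differed between the classes by its own test stood out on the log2 scale as carcinoma minus papilloma. The difference was 5.46 for Krt13, 1.98 for Gstm1, 1.59 for Prss35, 1.55 for Gstm2 and 1.30 for Gstm6. It was -4.40 for Chil3, -3.49 for Chia1, -2.04 for Nat8l, -2.03 for Nlrp10, -1.64 for Ndrg1, -1.62 for Plau, -1.57 for Bhlhe40 and -1.06 for Irf1, and -0.997 for both Gtf2e2 and Sorcs2. The median difference was 0.62 for matrix proteins, 0.47 for suprabasal genes, 0.29 for oxidative and xenobiotic genes and -0.33 for interferon-induced genes.

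A single value lay far from the rest in 13 of 216 groups of values, where 5% of groups, or 10.8, would do so by chance. The test takes 4 to 10 values, so the papilloma pairs were too many for it, and Tgfb1 was the only papilloma group tested. That 12 of the 13 were carcinoma groups and 1 a papilloma group therefore does not compare the classes. Pair 1687 with 221 stood apart for myoglobin (Mb), at 11.2 against -4.07 to 1.98 in the others, for Aldh3a1 at 3.43 against -0.51 to 0.71, for Ifi203 at 0.67 against -0.86 to -0.23, and for the adipocyte list mean at 1.16 against -0.29 to 0.16. The array of this pair, carcinoma 1, lacked 22.5% of its probes, against 3.63% to 7.78% on the other carcinoma arrays. Pair 170 with 242 stood apart for Hspe1 at 1.53 against -0.04 to 0.62, and for Prss35 at 2.79 against 0.75 to 1.46. Pair 236 with 241A stood apart for Mcpt2 at -1.79 against -0.28 to 0.76, and for Sorcs2 at -1.37 against -0.44 to 0.10, and its array, carcinoma 4, had a median as deposited of -0.15 against -0.03 to 0.004. Pair 236 with 257A stood apart for Cox6c at 0.48 against -0.89 to -0.33, and for the immediate-early list mean at -0.26 against 0.01 to 0.15. Among the 5 papilloma arrays that measured Tgfb1, papilloma 14 held 1.97 against 0.26 to 0.68 on the others.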

How the results depend on the processing

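The tumour share held at 0.2, the fits without the first range of experiment numbers and with the range as a fixed term, and 3 further settings of the dye-swap correlation were chosen after the results were seen. Of 222 values of named genes 3 took the other sign with a dye term, Acta2 and Eng in papillomas and Rps26 in carcinomas, none past the threshold without it, and Smad7 in carcinomas went from 0.05 to -0.13. The 26 gene results followed through the settings kept their signs. Under other settings they gave 318 values that kept their side of the threshold, 19 that came to pass it and 110 that ceased to, and with a tumour left out 465, 10 and 149. Where no reason is given for a changed count, the cause was not tested. Counts below are genes (limma) or lists (cameraPR) past an adjusted p of 0.05, beside 4 genes in papillomas, 6 in carcinomas, 23 for the difference and 1 for the mean of both, and 14, 9 and 4 lists.

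Equal spread gave 19 papilloma genes, and quantile normalization 27 and 2 for the mean. The dye term gave 2 carcinoma genes, 7 difference lists and a correlation between the classes of -0.058 in place of 0.12. The 5 pairs with both orientations, with 3728 genes, gave 0 genes in papillomas, carcinomas, the difference and the mean (509, 254, 423 and 313 unadjusted), 3 papilloma and 3 carcinoma lists and a correlation of -0.17, with fewer samples as the construction. Forward arrays alone gave 2 papilloma genes, 142 carcinoma genes and 216 for the mean. Independent pairs without weights gave 2 papilloma and 44 carcinoma genes, 8 difference lists and 4 genes for the mean. The bigenic tumour as the replicate gave 0 papilloma genes (623 unadjusted), 113 carcinoma genes, 14 difference genes, 9 difference lists and 0 for the mean (1346 unadjusted). Linked groups as the replicates, 7 in all, gave 0 genes in papillomas, carcinomas, the difference and the mean (583, 972, 492 and 1065 unadjusted), 9 papilloma lists and 9 difference lists. The monogenic tumour as a random block gave 51 carcinoma genes, 8 difference lists and 4 genes for the mean. An animal effect for shared numbers gave 0 papilloma genes (349 unadjusted), 9 difference genes, 7 difference lists and 0 for the mean (535 unadjusted). That model took an animal share of 0.15 and had a higher restricted likelihood than the main model. Classes fitted separately gave 0 carcinoma genes (499 unadjusted) and have no difference to test. The 3334 genes on every array gave 1 carcinoma gene, 14 difference genes and 0 for the mean (504 unadjusted), with fewer genes tested. Single probes gave 1 papilloma gene, and 1 probe per gene 14 carcinoma genes. The tumour share of 0.2 gave 1 papilloma and 7 difference genes. Without the first range there was 1 papilloma gene, 3 carcinoma and 3 difference genes, and 0 for the mean (535 unadjusted). The range as a fixed term over pairs gave 7 difference genes, 0 of them among the 23, in 6393 genes, while the 23 had a median of 0.96 times their difference and 1.39 times their SE.

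Leaving out each of 24 tumours moved the papilloma genes from 0 to 7 and lists from 7 to 16, the carcinoma genes from 2 to 81 and lists from 4 to 15, the difference genes from 1 to 33 and lists from 2 to 10, the genes for the mean from 0 to 36, and the correlation from -0.051 to 0.233. Array numbers are shared between the classes and were also taken as a pairing. Same-numbered arrays did not deviate together, at r from -0.32 to 0.14, so the numbers do not pair the tumours. As a replicate block over separate arrays they gave 31 difference genes against 49 without the block, 22 of them shared with the 23. The range of experiment numbers as a random block, with an estimated correlation of only 0.0056, gave 14 papilloma and 26 carcinoma genes. The dye-swap correlation of -0.13 was -0.34 over the 10% of probes with the largest ratios and from -0.128 with no centring to -0.154 over genes otherwise. The number of arrays limits the precision, and signal over background is unknown for these ratios.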

Other observations

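The tests in this part were planned, and the genes it names were chosen after their values were seen.

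Some genes that answer TGF-beta in many cell types were followed in both classes, although their list did not pass in papillomas, in carcinomas or for the difference (adjusted p = 0.247, 0.0779 and 0.564, cameraPR). In papillomas Bhlhe40 (0.80 ± 0.196), Smad7 (0.61 ± 0.181), Tgfbi (0.60 ± 0.18) and Skil, a nuclear repressor of Smad signalling (0.41 ± 0.158, 10 of 11 pairs), lay on the positive side on the log2 scale, while in carcinomas Smad7 was 0.05 ± 0.217, Skil -0.13 ± 0.197 and Tgfbi 0.19 ± 0.225. None passed for the difference between the classes except Bhlhe40 (adjusted p = 0.0291, limma), with Smad7 at 0.671, Tgfbi at 0.797 and Skil at 0.632.

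A few genes, among them members of the protease and cytokine lists, gave opposite signs in the classes without passing for the difference. Neither list passed for the difference (adjusted p = 0.726 and 0.654, cameraPR), nor cytokines in carcinomas (0.122), where the list mean was positive in 3 of 7 pairs, at 1.51, 1.06 and 0.995, and negative in 4. On arrays of the second range the carcinoma cytokine mean was -0.03, positive on 2 of 8, and the protease mean 0.23, positive on 3 of 8. Mmp9 was 1.28 ± 0.287 in papillomas and -0.56 ± 0.358 in carcinomas, a difference of -1.85 ± 0.459 (adjusted p = 0.0862, limma), and Serpinb2, an inhibitor of urokinase, was -0.79 ± 0.204 and 0.65 ± 0.255, a difference of 1.44 ± 0.327 (0.057). The chemokine Ccl8 was 1.14 ± 0.32 and -0.81 ± 0.40 (0.116), and the interferon-gamma induced chemokine Cxcl9 0.89 ± 0.503 and -1.75 ± 0.616 (0.245). Ccnd2 was -0.56 ± 0.145 in papillomas and 0.49 ± 0.192 in carcinomas, where it was positive in 6 of 6 pairs (0.0634 for the difference, limma). Vegfa was 0.33 ± 0.197 and -0.97 ± 0.245, and Lamb3 0.66 ± 0.219 and -0.63 ± 0.273, with adjusted p of 0.0765 and 0.144 for the difference. With a dye term Serpinb2 and Vegfa passed for the difference (adjusted p = 0.035 and 0.0368, limma). When every probe was tested as its own feature, 1 probe without a gene name passed for the difference, at -1.09 (adjusted p = 0.0461, limma).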
